A study of Homo sapiens with 6 samples.

How the data were processed

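Gene expression was measured in SKOV3, an established human ovarian adenocarcinoma cell line, on 6 Affymetrix arrays of total RNA. Per the labels' protocols, the cells were transiently transfected with a cationic lipid reagent and a small RNA against RELB or, as the control, against luciferase, and RNA was extracted with Trizol. RelB expression was examined 24 hours after transfection, and the labels do not say whether the RNA for the arrays was taken at that time. The sample names call the reagents shRNA, the growth protocol calls them siRNA, and the control samples carry the word vector in their characteristics. The groups are called siRELB and siLuc here, after the labels, with 3 arrays each. No label says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

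The deposited table holds log2 expression values for 33297 probe sets on each array. The submitters' processing notes name RMA (background correction, quantile normalization and probe set summarization), oligo and limma, without versions or settings. The log2 scale was read from the deposited values, which ran from 1.62 to 14.6 with array medians between 6.38 and 6.44 and no centring of genes or arrays to 0. Scanner files were not used here, so background correction, spot flags, slide and scan date could not be varied or tested. RMA fits all arrays together and draws their distributions towards one another, so a change in most transcripts at once would be reduced. An RMA value near the bottom of the range is mostly background, and differences between such values understate changes in RNA.

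Gene names came from the platform annotation supplied with the values. It gave 1 symbol for 19460 probe sets, several for 1754 and none for 12083; no gene was named from a probe set with several. Through the Entrez ID, 19429 of the 19460 probe sets matched a current gene record, and no symbol changed. The source names no genome build and gives no coordinates, so no positions are stated. One value per gene was needed for gene lists, and the probe set with the highest mean over the 6 arrays was taken, which gave 18417 genes.

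All 33297 probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), as siRELB minus siLuc with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. For RELB and the other NF-kB subunits a two-sided exact permutation test of the 6 array values was added; with 3 arrays against 3 it cannot give a p below 0.1. The 35 gene lists were tested as sets with limma's camera at a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry, each adjusted over the 35 lists. RELB was left out of every list. The test, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named RELB, the other NF-kB subunits, up to 12 genes per direction that passed the threshold with no overlap between groups (or, with too few, 6 per direction by smallest p, reported as not passing), and the 2 to 4 members with the smallest p of each list described. Any other gene named was chosen after its values were seen, and the text says so.

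On simulated data with each probe set's own mean and SD, the test of siRELB minus siLuc over 33297 probe sets recovered 118 of 200 probe sets changed 2-fold, 185 of 200 changed 4-fold and 198 of 200 changed 8-fold, with 3 to 5 false calls. When the same changes were added to the deposited values after removal of the group difference, 105, 194 and 200 of 200 were recovered. The 0 false calls there were fixed in advance, because no other probe set had a group difference left. The added changes also carried no sampling error, so this run is no measure of false calls or of full power. A shift of -0.5 (log2) placed on the 41 NF-kB target genes in simulated noise was recovered as a median of -0.49. The adjusted p was 1.35e-32 by camera, 0.00517 by camera with an estimated correlation and 0.000354 by fry. Camera with the preset correlation called 0 of the other 34 lists. The simulated noise, here and in the first run, was independent between probe sets. In the deposited values the estimated correlation between genes was 0.10 for NF-kB targets and 0.42 for histone genes. The shift also exceeded every list median observed (-0.20 to 0.20). This run therefore does not measure false calls or sensitivity in these data. The distance from the log2 difference to either end of its 95% confidence interval had a median of 0.32 over the probe sets with 1 symbol, a 1.24-fold change. Both the number of arrays and the spread between arrays within the labelled groups limit this precision.

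The replicate numbers in the sample names were checked for pairing. After subtraction of the group means, same-numbered arrays correlated at -0.32, -0.60 and -0.26 for numbers 1, 2 and 3, so the numbers were not taken to pair the arrays. Differently numbered arrays correlated at 0.34 to 0.44 where 1 of them was number 2, and at -0.22 and -0.27 otherwise. These values follow the way siRELB 2 and siLuc 2 part from their groups (see Results), so they cannot show that the numbers do not pair. Alternatives covered a filter on dim probe sets, a second quantile normalization, median centring, a floor at the 20th percentile, the variance model, array weights, a replicate block, each array left out in turn, a fold of at least 1.5 as a second criterion, the value per gene and the set test. Added after seeing the data were the first principal component as a covariate, leaving out siRELB 2 and siLuc 2 together, and testing the probe sets with 1 symbol alone. Some list members, such as classical HLA genes, share their probe sets with other genes or are not used here.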

Results

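Transcript levels were compared between SKOV3 ovarian carcinoma cells transfected against RELB, a subunit of the NF-kB transcription factors that acts mainly in the non-canonical pathway, and cells transfected against luciferase, which human cells lack. The comparison asked which transcripts differ when RELB is targeted. Each group held 3 arrays, and each array gave a log2 RMA value for every probe set. Array medians lay between 6.38 and 6.44, and pairs of arrays correlated at 0.981 to 0.995 over all probe sets. No pair of arrays was a duplicate: at most 31 values were identical in any pair.

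The correlations did not follow the labelled groups for siRELB 2 and siLuc 2. The highest value, 0.995, was between siLuc 1 and siLuc 3, and siRELB 1 and siRELB 3 correlated at 0.991. The array labelled siRELB 2 correlated at 0.994 with siLuc 1 and with siLuc 3, but at 0.984 with siRELB 1 and 0.988 with siRELB 3. The array labelled siLuc 2 correlated at 0.991 with siRELB 3 and 0.989 with siRELB 1, but at 0.987 with siLuc 1 and 0.985 with siLuc 3. The first principal component of the 6 arrays held 48.6% of the variance. On it siRELB 2, siLuc 1 and siLuc 3 lay at 39.1, 21.8 and 24.2, while siRELB 1, siRELB 3 and siLuc 2 lay at -30.1, -16.0 and -39.1. This was not a clean division: siRELB 3 correlated with siLuc 1 (0.991) and siLuc 3 (0.990) about as well as with siRELB 1 and siLuc 2 (0.991 each). The second component (19.8%) set siRELB 1 (-35.6) and siLuc 2 (27.5) at opposite ends.

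**Figure D1:**
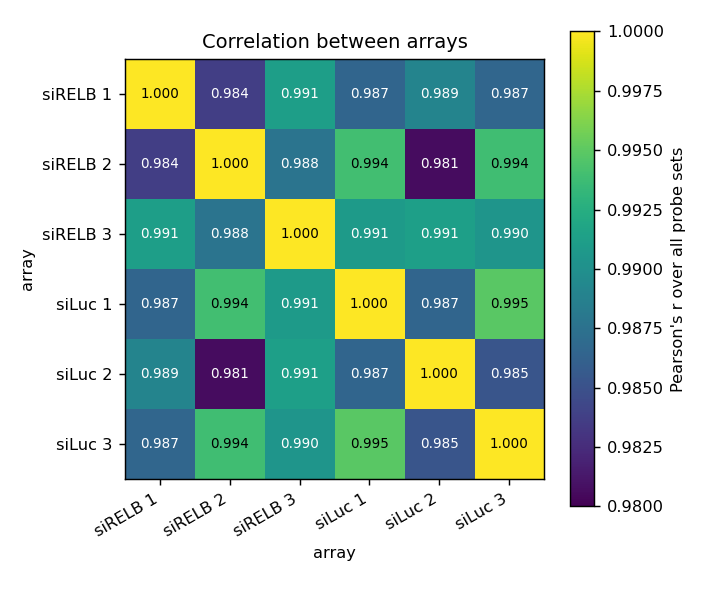
Pearson's r between each pair of the 6 arrays over all probe sets, as a colour scale from 0.98 to 1 with the value in each cell; rows and columns are arrays. The siRELB 2 array has its highest values with siLuc 1 and siLuc 3 (0.994), and the siLuc 2 array with siRELB 3 (0.991).

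RELB mRNA was not lower in the arrays labelled siRELB. Its probe set (8029580) averaged 7.99 ± 0.10 (SD, n = 3) in siRELB and 7.95 ± 0.16 (SD, n = 3) in siLuc. The difference was 0.04 ± 0.12 (log2, SE), or 1.03-fold, with a 95% confidence interval from -0.25 to 0.32, which spans a change of -15.7% to 24.8%. The interval leaves out a larger decrease in this measurement. An exact two-sided permutation test of the 6 values gave p = 0.8, and limma an adjusted p of 0.9997. The single values were 8.04, 7.88 and 8.05 in siRELB 1, 2 and 3 and 7.88, 8.13 and 7.84 in siLuc 1, 2 and 3. Because the targeted gene did not show the labelled difference, every direction below refers to arrays by their labels alone.

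The other 4 NF-kB subunit genes also differed by less than the spread between arrays. RELA, the main canonical subunit, was 0.09 ± 0.12 (log2, SE) higher in the arrays labelled siRELB, and NFKB1, which encodes p105 and p50, was 0.07 ± 0.10 higher. REL differed by -0.10 ± 0.21 and NFKB2, the precursor of RELB's partner p52, by -0.01 ± 0.25. Exact two-sided permutation tests gave p = 0.4 for RELA, p = 0.7 for REL, p = 0.5 for NFKB1 and p = 1 for NFKB2. NFKB2 varied within both groups, from 8.64 to 9.22 in siRELB and from 8.57 to 9.33 in siLuc. Of the 19 measured NF-kB subunits and regulators, 10 had a positive and 9 a negative difference, with a median of 0.01 (log2), and camera gave an adjusted p of 0.810. The members with the smallest p were CHUK, the IKK-alpha kinase of the non-canonical pathway (0.49 ± 0.28, SE), BCL3 (-0.28 ± 0.17) and BIRC2 (0.16 ± 0.10), none of which passed. Single arrays moved these: BCL3 was -0.090 without siRELB 1, and CHUK 0.25 without siLuc 1 and 0.75 without siLuc 2.

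**Figure D2:**
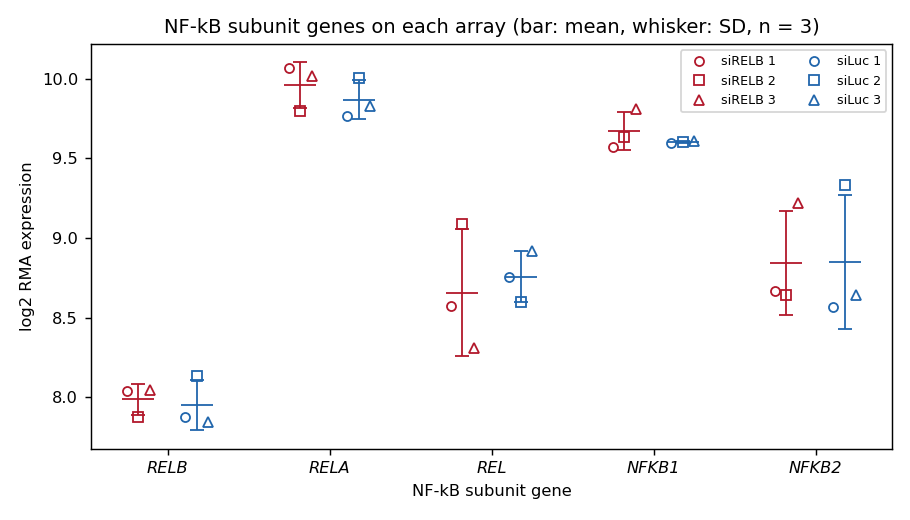
log2 RMA expression (vertical axis) of RELB, RELA, REL, NFKB1 and NFKB2 on each array; red points are siRELB, blue points siLuc, the marker shape gives the replicate number, bars are means and whiskers SDs over 3 arrays. RELB averaged 7.99 in siRELB and 7.95 in siLuc, and the 2 groups overlap for all 5 genes.

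No transcript passed the test between the labelled groups. With limma, 0 probe sets were higher and 0 lower in siRELB at an adjusted p under 0.05, and the smallest adjusted p was 0.9997. Before adjustment, 984 probe sets (2.96%) had a p under 0.05, where chance alone gives 5%, and 446 of these were higher and 538 lower in siRELB. In 2928 probe sets (8.79%) all 3 values of one group lay above all 3 of the other, against 10% by chance. Among probe sets with 1 symbol, only IL6 had a mean difference of at least 1 on the log2 scale, and its groups overlapped widely.

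The named genes nearest to the threshold had small differences. Higher in the arrays labelled siRELB, without passing, were PLA2G10, a secreted phospholipase (0.48 ± 0.10, log2, SE), NDUFAF1, an assembly factor of respiratory complex I (0.42 ± 0.09), SLU7, a splicing factor (0.47 ± 0.11), FAM177A1 (0.49 ± 0.11) and LINC00965 (0.39 ± 0.10, from 2 of its many probe sets, which share the same values). Lower without passing were CENPE, a kinetochore motor protein (-0.88 ± 0.23), PRLHR (-0.50 ± 0.12), UGT2B10 (-0.49 ± 0.12), MYCNOS (-0.44 ± 0.11), SERPINA2 (-0.37 ± 0.09) and OR5M3, an olfactory receptor (-0.51 ± 0.13). In all of these the 3 values of one group lay apart from the 3 of the other, and limma's adjusted p was 0.9997. Only NDUFAF1, SLU7 and FAM177A1 had a mean at or above the median of all probe sets; the others, CENPE and LINC00965 among them, lay below it, in the dim part of the range.

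NF-kB target genes did not shift between the labelled groups. Of 41 measured targets, 25 had a positive and 16 a negative difference, the median was 0.01 (log2), and camera gave an adjusted p of 0.543. The members with the smallest p were TRAF1 (0.35 ± 0.16, SE), the chemokine CCL20 (0.35 ± 0.22), the transcription factor IRF1 (-0.28 ± 0.18) and TNFAIP2 (-0.27 ± 0.21); without siRELB 1, IRF1 was -0.11 and TNFAIP2 -0.068. No member passed, over all probe sets or adjusted over the list alone. IL6, an inflammatory cytokine named here after its values were seen, read 10.4, 7.35 and 9.55 in siRELB 1, 2 and 3 and 7.39, 9.42 and 7.40 in siLuc 1, 2 and 3, a difference of 1.02 ± 0.87 (SE). CXCL8, another cytokine chosen the same way, read 12.1, 10.8 and 11.998 in siRELB against 10.8, 12.1 and 11.0 in siLuc. Without the siLuc 2 array the list's median was 0.070 with an adjusted p of 0.0343 by camera, and it also passed without both siRELB 2 and siLuc 2. With both left out, the labelled groups lie on opposite sides of the first principal component. That fit therefore cannot tell a difference between the labels from that component. Of 14 non-canonical targets, 5 were positive and 9 negative, with a median of -0.03 and an adjusted p of 0.98; UPP1 (0.30 ± 0.27) and LAMB3 (0.24 ± 0.25) had the smallest p.

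Of the 35 gene lists, 5 passed camera with the preset correlation, and none held with an estimated one. Camera with an estimated correlation called 0 lists in all 10 splits of the arrays, 3 against 3 (see Other observations). These include a split with 1900 probe sets past the threshold, so the loss of a list in that form says little. Histone genes were lower in the arrays labelled siRELB: 31 of 36 had a negative difference, with a median of -0.20 (log2) and an adjusted p of 1.63e-08. H2AC4 (-0.29 ± 0.12, SE), H1-2 (-0.26 ± 0.11), H1-1 (-0.38 ± 0.16) and H2BC14 (-0.34 ± 0.15) had the smallest p; histone genes are near-identical copies, so probes may not separate them. Ribosome biogenesis genes and MYC targets were higher, 24 of 28 with a median of 0.20 and an adjusted p of 1.32e-06, among them WDR43 (0.38 ± 0.15), the nucleolar protein NCL (0.27 ± 0.12), the helicase DDX21 (0.55 ± 0.25) and NOLC1 (0.31 ± 0.15). With an estimated correlation the adjusted p was 0.873 for both lists. No single member of either passed, over all probe sets or adjusted over the list alone.

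The other lists that passed with the preset correlation were also higher in the arrays labelled siRELB. DNA replication genes had 33 of 39 positive differences, with a median of 0.09 (log2) and an adjusted p of 0.000215. The DNA polymerase subunit POLE2 (0.28 ± 0.10, SE), MCM10 (0.43 ± 0.17), RFC3 (0.19 ± 0.09) and CLSPN (0.38 ± 0.20) led it. Mesenchymal genes and their regulators had 24 of 34, with a median of 0.16 and an adjusted p of 0.00456, led by fibrillin FBN1 (0.30 ± 0.11), fibronectin FN1 (0.48 ± 0.23), the collagenase MMP2 (0.27 ± 0.13) and the repressor ZEB2 (0.50 ± 0.25). Heat shock proteins had 15 of 17, with a median of 0.15 and an adjusted p of 0.00799, led by DNAJB6 (0.32 ± 0.12, on the brighter of its probe sets), HSPH1 (0.21 ± 0.14), HSPB1, which differed the other way (-0.19 ± 0.13), and HSP90AA1 (0.15 ± 0.10). With an estimated correlation the adjusted p was 0.873 for DNA replication, 0.890 for mesenchymal genes and 0.868 for heat shock proteins, and no member passed, over all probe sets or adjusted over the list alone. The estimated correlation was 0.078 for DNA replication and 0.24 for mesenchymal genes, above the preset 0.01. For heat shock proteins it was -0.005, below the preset, so a higher correlation between genes does not account for that loss.

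Single arrays carried much of the histone, ribosome biogenesis, mesenchymal and heat shock shifts. Histone, ribosome biogenesis and DNA replication lists passed with each array left out in turn, DNA replication with medians from 0.078 to 0.11 (log2). On the siRELB 1 array, histone genes lay 0.30 below their mean over the 6 arrays (log2), ribosome biogenesis genes 0.33 above and mesenchymal genes 0.30 above. Without siRELB 1 the medians were -0.081, 0.095 and 0.054, and the mesenchymal list no longer passed (adjusted p of 0.233). Without siRELB 2 the same 3 medians were -0.32, 0.31 and 0.25. The heat shock list no longer passed without siRELB 2 (0.107, adjusted p of 0.0505) or without siLuc 2 (0.061, adjusted p of 0.0514). With the preset correlation, 13 lists passed without siRELB 2 and 17 without siLuc 2, in place of 5. With both left out 17 passed, and heat shock was not among them. In that fit the labelled groups lie on opposite sides of the first principal component, so it cannot tell the labels from that component. Results with an estimated correlation were not kept for fits with arrays left out. With all 6 arrays that form left 0 lists.

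**Figure D3:**
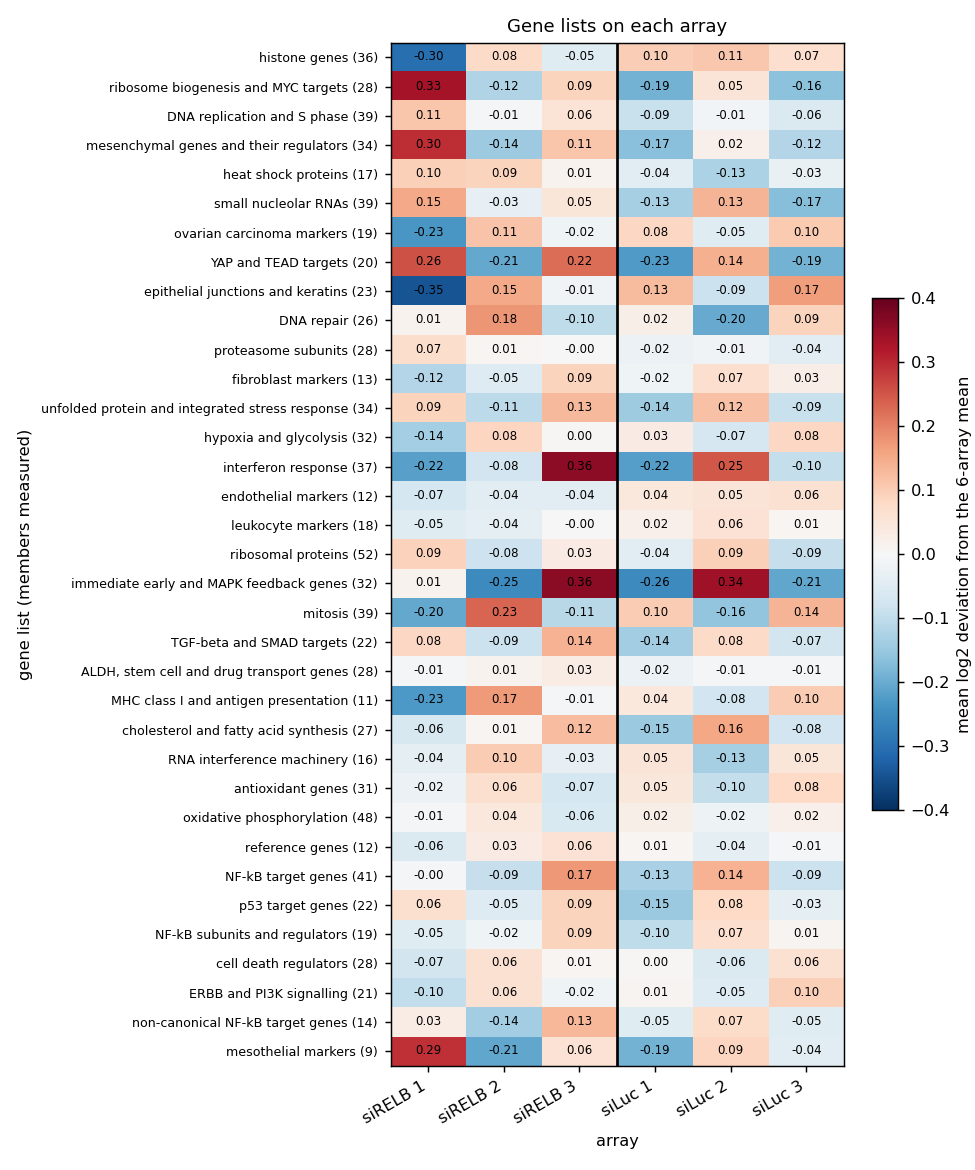
Mean log2 deviation of each gene list (rows, with the number of members measured) from its mean over the 6 arrays, on each array (columns; the line parts siRELB from siLuc), as a colour scale from -0.4 to 0.4 with the value in each cell. Immediate early genes lie at 0.36 on siRELB 3 and 0.34 on siLuc 2, but at -0.25 on siRELB 2 and -0.26 on siLuc 1.

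The other 30 lists did not pass, with medians from -0.12 to 0.10 (log2) and adjusted p from 0.0622 to 0.98. In the interferon response list, 26 of 37 genes were positive, with a median of 0.08 and an adjusted p of 0.381; the double-stranded RNA sensors EIF2AK2 (0.21 ± 0.10, SE) and IFIH1 (0.24 ± 0.13) had the smallest p. Immediate early and MAPK feedback genes had a median of 0.09 (21 of 32 positive, adjusted p of 0.451), with SPRY2 at 0.28 ± 0.15 and DUSP2 at -0.23 ± 0.16. In the list of YAP and TEAD targets, 16 of 20 genes were positive (median of 0.10, adjusted p of 0.0683), with CRIM1 at 0.31 ± 0.15 and AMOTL2 at 0.21 ± 0.14. For mitosis the median was -0.01, with 24 of 39 negative and an adjusted p of 0.451; CENPE, its lowest p, gave an adjusted p of 0.252 over the list alone, and CENPF differed by -0.57 ± 0.34. Epithelial junction genes and keratins had 18 of 23 negative (median of -0.07, adjusted p of 0.0795), with CLDN3 at -0.34 ± 0.12 and DSC2 at 0.37 ± 0.14. Ovarian carcinoma markers had 15 of 19 negative (median of -0.12, adjusted p of 0.0637), with CLDN3 and KLK10 (-0.21 ± 0.09) first. Both lists passed with the preset correlation without dim probe sets, after quantile normalization and with median centring. Results with an estimated correlation were kept for the values as deposited only, where camera gave an adjusted p of 0.890 and 0.873. In the list of ALDH, stem cell and drug transport genes, 16 of 28 were positive (median of 0.02, adjusted p of 0.482), with CD24 at 0.32 ± 0.13 and ABCG2 at 0.19 ± 0.12. Cholesterol and fatty acid synthesis genes had a median of 0.04 (adjusted p of 0.522), with SQLE at 0.25 ± 0.10 and PMVK at -0.27 ± 0.14. Across all lists, 0 of 891 distinct members passed over all probe sets, and 0 passed adjusted over the list alone, while 14 had an unadjusted p under 0.05. Of these 30 lists, 15 passed in at least 1 fit with a single array left out: with the preset correlation, immediate early, YAP and TEAD, mitosis, epithelial and ovarian lists passed without siRELB 2 and also without siLuc 2. The interferon list passed without siRELB 1 and without siLuc 2, and the cholesterol list without siLuc 2. DNA repair passed without siRELB 3, without siLuc 1 and without siLuc 3, and MHC class I without siRELB 2. The others were NF-kB targets, unfolded protein response, hypoxia, antioxidant, ribosomal protein and small nucleolar RNA lists.

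Markers of other cell types did not separate the labelled groups. The list medians were -0.06 (log2) for fibroblast, -0.02 for leukocyte, -0.04 for endothelial and 0.05 for mesothelial markers, with adjusted p of 0.340, 0.410, 0.381 and 0.98. The members with the smallest p were the fibroblast genes THY1 (-0.28 ± 0.09, SE) and COL1A1 (0.29 ± 0.17), and the leukocyte genes CD14 (-0.34 ± 0.13) and ITGAM (-0.23 ± 0.13). For endothelium they were CLDN5 (-0.24 ± 0.13) and EMCN (-0.30 ± 0.18), and for mesothelium KRT5 (-0.36 ± 0.15) and MSLN (-0.17 ± 0.10). Reference genes had a list median of 0.02, with HPRT1 at 0.19 ± 0.09, TFRC at 0.17 ± 0.09 and GAPDH at -0.10 ± 0.10.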

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

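The count of probe sets past the threshold stayed at 0 in both directions under all 17 alternatives tried, and the counts at an unadjusted p under 0.05 ran from 396 without dim probe sets to 5270 without siRELB 2 and siLuc 2. That setting, the first principal component as a covariate (2617) and the probe sets with 1 symbol alone (492) were added after seeing the data. Counts without dim probe sets and with 1 symbol alone came from fewer probe sets. The counts with array weights (3558), with the covariate, without siRELB 2 (1793) and without both arrays exceeded the 5% that chance alone gives. Without both arrays the labelled groups lie on opposite sides of the first principal component, so that setting cannot tell the labels from it. With the replicate block, 0 probe sets passed and 456 had an unadjusted p under 0.05; RELB stayed at 0.04, and no same-numbered pair correlated above 0. The RELB difference ran from -0.02 to 0.18 (log2) over 16 alternatives, positive in 14, with limma's adjusted p from 0.427 upward. None of the 152 genes followed passed under any alternative. These were RELB, the other NF-kB subunits, the genes nearest to the threshold and the 4 members with the smallest p of each list. Genes named after their values were seen were not added to them. A difference changed sign in 16 of 2412 values, 6 of them of NFKB2. Leaving out 1 array moved 111 of the 152 by over 1.5 times at least once. With the preset correlation, the NF-kB target list, at 0.01, passed camera with array weights (0.12), without siLuc 2 (0.070) and without both siRELB 2 and siLuc 2 (0.088). Its median ran from -0.019 to 0.088 with single arrays left out. With an estimated correlation, camera gave this list an adjusted p of 0.890. Results in that form were kept only for all 6 arrays without weights. Camera with an estimated correlation and fry ended all 5 list calls at unchanged medians: -0.20 for histones, 0.20 for ribosome biogenesis, 0.090 for DNA replication, 0.16 for mesenchymal genes and 0.15 for heat shock. Heat shock was also lost without dim probe sets (0.13), with array weights (0.073) and without both siRELB 2 and siLuc 2 (0.028), with 0.061 to 0.18 when single arrays were left out; mesenchymal genes then ran from 0.054 to 0.25. The causes of these changes were not tested. Of 630 list values, 551 stayed on their side of the threshold, 16 fell below it and 63 rose above it, with 19 lists passing with array weights; epithelial and ovarian carcinoma lists rose without dim probe sets, after quantile normalization, with median centring, with array weights, without siRELB 2, without siLuc 2 and without both, the ovarian list also with the replicate block. The median changed sign in 72 of the 630. Sign changes in genes or lists that passed neither way were not counted as reversals. Background correction and slide could not be varied on summarized values, and dim probe sets limit what low transcripts can show.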

Other observations

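The transcripts that varied most over the 6 arrays varied within both labelled groups. The 24 genes with the highest SD over all arrays, among those with a mean at or above the median, included stress and growth-response genes. EGR1, an immediate early transcription factor, read 10.4, 8.74 and 11.5 (log2) in siRELB 1, 2 and 3 and 8.90, 11.4 and 8.89 in siLuc 1, 2 and 3. In the same order, GADD45A, a growth arrest gene, read 11.0, 8.86, 11.3, 8.76, 11.4 and 8.70. The stress-induced transcription factor ATF3 read 7.14, 5.96, 7.95, 5.91, 8.25 and 6.06. CCN1, a matricellular protein and YAP target, read 9.94, 7.67, 9.98, 7.47, 10.02 and 7.60, and ANKRD1, another YAP target, 8.50, 5.76, 9.11, 6.18, 8.96 and 5.88. HMOX1, heme oxygenase, read 10.4, 7.62, 9.05, 7.86, 9.28 and 7.80.

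Other genes of this set ran the opposite way across the arrays. SERPINB3, a serpin also known as squamous cell carcinoma antigen, read 5.57, 8.40 and 5.72 in siRELB 1, 2 and 3 and 7.65, 5.32 and 8.30 in siLuc 1, 2 and 3. In the same order, CP, ceruloplasmin, read 8.003, 11.1, 9.49, 10.5, 8.90 and 10.9, and the amino acid transporter SLC7A2 read 6.99, 10.1, 8.21, 9.77, 7.79 and 9.91. TRIM31, a ubiquitin ligase, read 5.99, 8.97, 7.07, 8.76, 6.65 and 8.90. CDH1, the epithelial cadherin, which is not among the 24, read 6.33, 8.53, 7.37, 8.30, 7.06 and 8.55. Apart from CDH1, these genes were chosen by their spread, without regard to group; all, with CDH1, were chosen after the values were seen. The array siRELB 1 lay at the far end for SERPINA3 (7.82, with 9.46 to 10.5 on the other arrays) and TMTC1 (5.26, with 7.005 to 8.03).

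All tests below were chosen after the result was seen, except the count of gene lists over splits and the test of quantile normalization. The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The labelled split gave 0 probe sets at limma's adjusted p under 0.05, so all 10 splits gave at least as many, and the highest of the others gave 1900. That one set siRELB 1, siRELB 3 and siLuc 2 against siRELB 2, siLuc 1 and siLuc 3, and the remaining 8 gave 0; it is the split by sign of the first principal component, so its count restates that component and is no separate support. Gene lists were also called over the splits by camera with the preset correlation. The labelled split gave 5, 9 of the 10 splits gave at least as many, and the highest of the others gave 17. With an estimated correlation all 10 splits gave 0 lists, also the one with 1900 probe sets. The 0 lists of the labelled split in that form therefore say little.

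The first principal component parts the arrays into 2 sets that cross the labelled groups, though siRELB 3 correlated with siLuc 1 (0.991) and siLuc 3 (0.990) more than siRELB 1 did with siLuc 2 (0.989). Differences in the distribution of values between arrays predict under 25% of the variance on the first principal component after a second quantile normalization. That component still held 48.18%, which argues against distribution differences left in the deposited values. RMA had already drawn the arrays' distributions together, so the test says nothing about differences before that step. An exchange of the labels of siRELB 2 and siLuc 2 is a candidate explanation, as that exchange turns the labelled split into the one with 1900 probe sets, a count that any cause of this component would give. With the exchange RELB would be 0.207 (log2) higher, not lower, in the arrays then called siRELB. The unadjusted 95% interval ran from 0.02 to 0.39, and limma's adjusted p was 0.163. This argues against an exchange together with a net lowering of RELB mRNA in those arrays. A lowering offset by whatever else parts the 2 sets of arrays cannot be told from these values. An exchange whatever happened to RELB mRNA, an unlabelled processing batch and a difference between cultures cannot be told apart here, because the labels give no batch, and no biological explanation beyond the transfection is named by the design.

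The spread between arrays fell on some gene groups more than on others, with 13 of 35 lists above random lists at an adjusted p under 0.05. Against 10000 random lists matched on mean level, the median SD over the 6 arrays was 0.30 for immediate early and MAPK feedback genes (0.16 for random lists, adjusted p of 0.000875 over 35 lists). It was 0.27 for NF-kB targets (adjusted p of 0.000875) and 0.24 for YAP and TEAD targets (adjusted p of 0.0136). Interferon response genes (0.28) and small nucleolar RNAs (0.24) had the same adjusted p of 0.000875, whose unadjusted p of 0.0001 is the smallest these random lists can give. Reference genes (0.10), oxidative phosphorylation (0.11) and DNA replication (0.11) lay below their random lists. Ribosome biogenesis, histone and mesenchymal lists (0.0095 each), epithelial junctions, mitosis, the unfolded protein response, ovarian carcinoma markers and cholesterol synthesis also passed, while heat shock proteins (adjusted p of 0.343) and hypoxia genes (0.911) did not. The cause was not tested. Genes of a list move together, while the random lists were drawn as independent genes. These p-values are therefore likely too small, and the 13 lists past the threshold may be too many. They describe the spread over the 6 arrays and not a treatment.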
